A study of Mus musculus with 32 samples.

How the data were processed

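RNA from sorted mouse microglia was sequenced in 32 libraries, 1 per mouse. Per the labels' protocols, single-cell suspensions were sorted for DAPI-negative, CD11b-positive cells with intermediate CD45, and 10000 to 50000 cells per mouse were taken. RNA with an integrity number of at least 7 was amplified with SMART-Seq v4, and Nextera XT libraries were sequenced as paired reads. The kit does not mark strand. Per the submitters' processing notes, the genome build was mm10 and the tools were STAR and HTSeq, with no versions, annotation or strand setting given. The deposited table holds read counts per gene as the authors made them, with Ensembl mouse identifiers. Its values are whole numbers with no normalization applied, 1 column per library, and 48795 genes, of which 40164 had at least 1 count.

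Total counts per library in units of 1e6 ranged from 28.5 to 47.6 with a median of 35.8. Reads amplified from 10000 to 50000 cells without molecular identifiers are not independent molecules, so counts at this depth give the counting error only, and the spread between mice was estimated from the replicates. Gene symbols came from the deposited table, and 48349 identifiers (99.1%) matched the reference table of gene names. Positions on GRCm38 (mm10) came from GENCODE M21, which held 18785 (99.7%) of the tested genes. Labels were checked with the genes that carry the CreER insertion and with sex-linked genes: Xist had at most 6 counts in any library and Ddx3y had 626 to 3371, for mice that are all labelled male. No pair of libraries in a group was a copy of another (50 pairs, chi-square per degree of freedom of 6.20 to 69.7).

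Genes were kept with edgeR's filterByExpr by group (18847 genes) and scaled with TMM factors in edgeR 4.0.16 under R 4.3.3. A quasi-likelihood model with 1 mean for each of the 8 groups (line by treatment) was fitted to all 32 libraries, so that the groups shared 1 estimate of the spread. The biological coefficient of variation was 0.187. Each comparison was tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over the 18847 genes and a threshold of 0.05 on the adjusted p. Standard errors of log2 fold changes came from the same fit. The comparisons were tamoxifen versus oil in each of the 4 lines, the mean of those 4 effects, the difference of the effects among lines, the difference between the Jung and Littman effects, and the 6 pairs of lines among oil mice. No batch, litter or day is given in the labels, so none was a term of the model.

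The comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, in each comparison, the carrier genes Tmem119, Cx3cr1 and Hexb. It also named the 12 largest rises and 12 largest falls among genes that passed, had a mean log2 CPM of at least 1 and did not overlap between the groups, leaving out unnamed gene models. Where fewer than 10 genes passed, and in the tests of a difference between effects, it named the 10 smallest p values. From each list discussed it named up to 4 members with the smallest p and any member that passed. Where space was short, only some genes of a ranking were named, and these were not always the ones at its top. Dnase2a, Crtap, Clasp2, Dock8 and the clock genes fell outside the rule and were chosen after their values were seen.

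The 22 gene lists were homeostatic microglia, type I interferon response, disease-associated microglia, p53 and DNA damage response, cell cycle, immediate early and dissociation response, inflammatory cytokines and NF-kB, antigen presentation, estrogen response, cholesterol synthesis and lysosome, and markers of 11 other cell types (border-associated macrophage, monocyte, neutrophil, lymphocyte, astrocyte, oligodendrocyte, oligodendrocyte precursor, neuron, endothelial and mural, choroid plexus and ependyma, and erythroid). Lists were tested against all other genes with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the 110 tests of the tamoxifen family, the 132 of the line family and the 22 of the Jung and Littman difference. The same tests with the correlation estimated from the residuals were an alternative. List scores per library were the mean log2 CPM (prior count 2) of the tested members, compared within a line by a two-sided exact permutation test. Genes within 5 Mb of each carrier gene were compared with all others by a two-sided Fisher's exact test.

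Alternatives were DESeq2's size factors in edgeR, no filter on low counts, a strict filter (CPM over 1 in at least 3 libraries), DESeq2 1.42.0, limma voom with quality weights, a fit of only the 2 groups compared, leaving out each library in turn, a prior count of 0.5 and the median over members for scores, calls at an adjusted p of 0.01 for replication, and windows of 2 and 10 Mb. Alternatives chosen after the data were seen were a term for 2 sets of Jung libraries (replicates 9 to 14 and 15 to 17), the Jung tamoxifen comparison in replicates 9 to 14 only, the line comparisons without replicates 9 to 14, lists without the carrier genes, and a permutation over all 4 lines together. The 2 sets of Jung libraries were inferred from the data, not from the labels.

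The analysis was tested on simulated counts with 200 genes changed together per comparison, drawn from genes with a mean CPM of at least 2. Counts were drawn independently for each gene and library, with no sets of libraries or outlying libraries. For tamoxifen versus oil, the share of 1.5-fold changes recovered was 74.6% in the Tmem119 line, 73.1% in Jung, 61.2% in Littman and 46.3% in Hexb, and the share of 2-fold changes was 97.0%, 97.0%, 92.5% and 89.6%. For line differences in oil mice, 1.5-fold changes were recovered at 79.1% for Tmem119 versus Jung, 61.2% for Tmem119 versus Hexb and 62.7% for Jung versus Littman, and 2-fold changes at 85.1%, 92.5% and 95.5%. Sequence reads were not realigned, and no deposited sample was left out.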

Results

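The series compared 4 mouse lines in which a tamoxifen-inducible Cre recombinase (CreER) is expressed from a microglial gene. CreER was carried at Tmem119, at Cx3cr1 in 2 separate alleles called Jung and Littman, or at Hexb. Per the labels, mice were heterozygous for the Tmem119 and both Cx3cr1 alleles and homozygous for the Hexb allele. Male mice received tamoxifen at 100 mg/kg daily from postnatal day 28 to 31, or oil. Microglia, the resident macrophages of the brain, were sorted 4 weeks later at day 56. Tamoxifen and oil groups held 4 and 4 mice in the Tmem119 line, 5 and 4 in Jung, 5 and 4 in Littman, and 3 and 3 in Hexb. Replicate numbers were unique in the series and are used below to name libraries. Total counts in units of 1e6 (mean and SD) were 30.3 ± 1.99 in Tmem119 oil, 36.8 ± 4.51 in Tmem119 tamoxifen, 36.0 ± 3.46 in Jung oil, 38.9 ± 5.86 in Jung tamoxifen, 36.2 ± 2.41 in Littman oil, 33.2 ± 1.97 in Littman tamoxifen, 36.6 ± 1.16 in Hexb oil and 35.0 ± 2.00 in Hexb tamoxifen libraries. Adjusted p values for genes are from edgeR's quasi-likelihood test over 18847 genes, and log2 fold changes are given with their standard error. Adjusted p values for lists are from camera. All list calls given below, 24 of 110 tamoxifen tests and 48 of 132 line tests, were made at the preset correlation, and 0 of each family passed with an estimated correlation. The number at an unadjusted p under 0.05 is given for genes beside each count of 0.

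Each carrier gene was lowest in its own line. Tmem119, a microglial membrane protein (chromosome 5, 113793729 to 113800516, minus strand), had a mean log2 CPM of 12.45 ± 0.031 (SD, n = 4) in Tmem119 oil mice, 13.25 ± 0.17 (n = 4) in Jung, 12.98 ± 0.20 (n = 4) in Littman and 12.69 ± 0.036 (n = 3) in Hexb. Cx3cr1, the fractalkine receptor (chromosome 9, 119901616 to 120069879, minus strand), was at 11.95 ± 0.21 in Jung and 11.85 ± 0.15 in Littman oil mice against 12.83 ± 0.089 in Tmem119 and 12.61 ± 0.087 in Hexb. It was 1.82-fold higher in Tmem119 than in Jung mice (adjusted p = 2.15e-06) and 1.96-fold higher than in Littman mice (adjusted p = 1.29e-07). Hexb, a subunit of a lysosomal hexosaminidase (chromosome 13, 97176331 to 97198357, minus strand), was at 8.52 ± 0.25 in Hexb oil mice and 14.28 ± 0.029, 14.40 ± 0.065 and 14.30 ± 0.13 in Tmem119, Jung and Littman oil mice. Its level in the other lines was 53.5-fold (Tmem119), 58.4-fold (Jung) and 54.5-fold (Littman) that of the Hexb line. The lines carry 1 altered copy of Tmem119 or Cx3cr1 and 2 of Hexb. In each case every oil library of the carrier line lay below every oil library of the lines without the insertion. Of 18 tests (3 genes in 6 line pairs), 12 passed. None of the 3 genes passed between Jung and Littman, where Tmem119 was 0.27 ± 0.090 higher in Jung (adjusted p = 0.0753). Tamoxifen changed none of the 3 genes in any line, and the effects farthest from 0 were -0.23 ± 0.085 for Tmem119 in Jung (adjusted p = 0.593) and -0.23 ± 0.091 for Hexb in the Hexb line (adjusted p = 0.722).

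**Figure D1:**
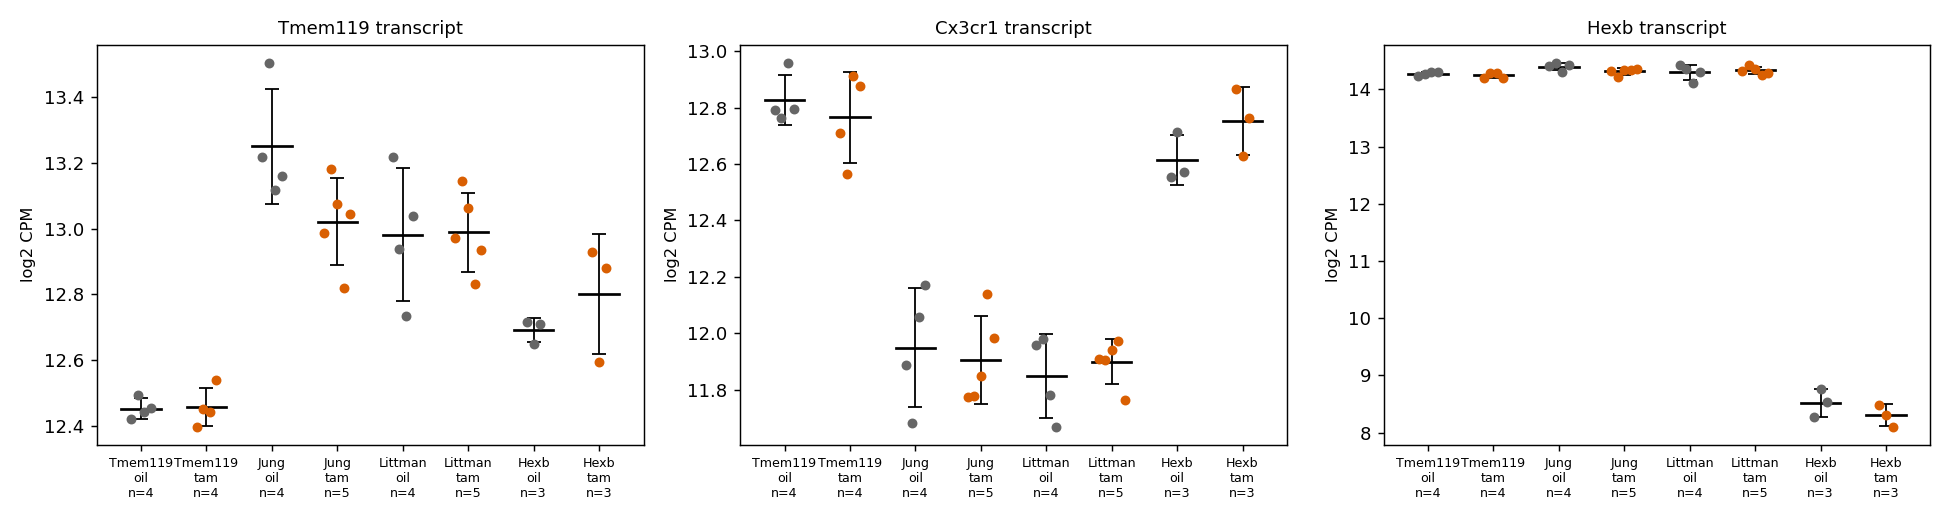
Level of the 3 carrier genes (log2 CPM, 1 point per library; grey, oil; orange, tamoxifen; bars, mean and SD) in the 8 groups. Tmem119 oil libraries sit at a mean of 12.45 for Tmem119, Cx3cr1 is near 11.95 in Jung and 11.85 in Littman oil libraries, and Hexb is at 8.52 in Hexb oil libraries against 14.28 to 14.40 in the others.

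Gfm2, a mitochondrial translation factor gene that overlaps Hexb on the opposite strand (97137937 to 97181195), had the same pattern. Its log2 fold change against the Hexb line was 5.57 ± 0.10 in Tmem119 (adjusted p = 4.63e-30), 5.69 ± 0.10 in Jung and 5.62 ± 0.10 in Littman oil mice. Gfm2 counts were 42.0 to 43.9% of Hexb counts in the 26 libraries of the other lines and 47.0 to 52.0% in the 6 Hexb libraries. The kit does not mark strand, so reads from the shared stretch cannot be assigned to either gene and the Gfm2 values are uncertain.

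At 4 weeks after tamoxifen, no gene passed in any line by edgeR. The counts at an unadjusted p under 0.05 were 639 in the Tmem119 line, 1431 in Jung, 578 in Littman and 1234 in Hexb, where 942.35 were expected with no effect. By limma voom 0 genes passed in each line, and by DESeq2 0 passed in Tmem119, 0 in Jung, 2 in Littman and 9 in Hexb. The question these comparisons address is whether tamoxifen, with CreER present, leaves a lasting change in the microglial transcriptome. At these group sizes 2-fold changes were recovered in simulated data at 89.6% (Hexb) to 97.0% (Tmem119 and Jung), and 1.5-fold changes at 46.3% (Hexb) to 74.6% (Tmem119). These shares apply to 200 genes changed together with a mean CPM of at least 2, in independent simulated counts. With fewer changed genes or lower counts, recovery may be lower. None of the tamoxifen tests of the estrogen response (smallest adjusted p = 0.193), lymphocyte (0.358), oligodendrocyte (0.0522), oligodendrocyte precursor (0.307), endothelial and mural (0.188) and choroid plexus and ependyma lists (0.188) passed.

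In the Tmem119 line, cell cycle genes were higher after tamoxifen as a list (31 of 37 members, median log2 fold change 0.25, adjusted p = 2.37e-04; adjusted p = 0.778 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had a log2 fold change of 2.77 ± 0.76 (n = 4 and 4) and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0328), with 0 members passing over all genes. Mki67, the proliferation marker Ki-67, was at 1.53 ± 0.75 and did not pass. The list score was 0.83 ± 0.10 (SD) in oil and 1.29 ± 0.12 in tamoxifen mice, with no overlap between the groups (exact permutation p = 0.0286, the smallest that 4 against 4 can give; Benjamini-Hochberg 0.943 over all lists and lines). The score of disease-associated microglia genes, a set linked to neurodegeneration and ageing, was 0.15 higher with the same exact permutation p of 0.0286, and it did not pass as a camera list. Among the genes with the smallest p were Ppm1f, a protein phosphatase (0.51 ± 0.12), Lrrc9 (1.36 ± 0.34), Aebp1 (2.36 ± 0.59) and Nudt12 (1.17 ± 0.30), none of which passed. Without replicate 1, Ppm1f alone passed (0.67, adjusted p = 0.00208). The cell cycle call was lost with no filter on low counts (adjusted p = 0.189), and Ube2c and Mki67 had low mean log2 CPM (-1.19 and -0.26). The tamoxifen libraries of this line also detected more genes on average (24570 to 32493 against 23927 to 26751 in oil) and more olfactory and vomeronasal receptor genes (143 to 596 against 105 to 214), at 13.0 to 74.7 against 10.2 to 22.6 CPM in sum.

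In the Jung line, antigen presentation genes were lower after tamoxifen as a list (20 of 22 members, median -0.18, adjusted p = 1.46e-04; adjusted p = 0.717 with an estimated correlation). So were lysosome genes (27 of 34, median -0.092, adjusted p = 3.53e-04; adjusted p = 0.778 with an estimated correlation). No member passed singly. Psmb8, a subunit of the immunoproteasome, was at -0.23 ± 0.093 and Tapbp, which loads peptide on MHC class I, at -0.19 ± 0.081 (n = 5 and 4). Among lysosome genes, the heparan sulfatase Sgsh was at -0.30 ± 0.094 and the ganglioside activator Gm2a at -0.21 ± 0.069. The antigen presentation call was lost without replicate 12 (adjusted p = 0.520). Markers of monocytes (11 of 11 lower, median -1.09, adjusted p = 0.0436) and neutrophils (11 of 12 lower, median -0.98, adjusted p = 0.0192) also passed as lists, with adjusted p = 0.882 and 0.778 with an estimated correlation. For example, Treml4 was at -1.21 ± 0.74 and Plac8 at -1.10 ± 0.68, and no marker passed singly. The monocyte call was lost without replicate 11, 12, 14, 15 or 16 (adjusted p = 0.175 to 0.420) and with a term for the 2 sets of Jung libraries (0.327). The neutrophil call was lost without replicate 14, 15 or 16 (0.0877 to 0.255). These marker scores split the Jung libraries by replicate number: monocyte scores were 2.96 to 4.08 in replicates 9 to 14 and -0.52 to -0.10 in replicates 15 to 17, with tamoxifen and oil mice in each set. Among the genes with the smallest p were Tmem38a (-0.66 ± 0.14), Cdv3 (0.75 ± 0.17), the chromatin reader Brd3 (0.40 ± 0.095) and the transcription factor Atf1 (0.50 ± 0.12), none of which passed. Without replicate 16, Cdv3 (0.89) and Dock8 (0.63) passed, both with an adjusted p of 0.0273.

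In the Littman line, all 37 cell cycle genes were higher after tamoxifen (median log2 fold change 0.70, adjusted p = 2.53e-25; adjusted p = 0.156 with an estimated correlation). Of these, 15 passed when adjusted over the list alone and 0 over all genes. The replication helicase subunit Mcm2 was at 1.00 ± 0.25, the mitotic motor Cenpe at 1.73 ± 0.57, the ribonucleotide reductase subunit Rrm1 at 0.24 ± 0.074 and the mitotic kinase Cdk1 at 0.57 ± 0.18 (n = 5 and 4). Cell cycle scores were 1.87, 0.84, 1.02, 2.40 and 2.52 in tamoxifen replicates 18, 20, 21, 23 and 24 and 0.90, 0.82, 1.44 and 1.41 in oil replicates 19, 22, 25 and 26, a difference within the spread (0.59, exact permutation p = 0.206). Interferon response genes were also higher as a list (36 of 40, median 0.18, adjusted p = 1.89e-06; adjusted p = 0.717 with an estimated correlation), with the antiviral Rsad2 at 0.67 ± 0.32 and Lgals3bp at 0.26 ± 0.14. Cdkn1a, which encodes the p53 target and cell cycle inhibitor p21, had a log2 fold change of 1.36 ± 0.26 with no overlap between the groups, as 1.59% of genes would by chance. It did not pass in the fit of all libraries (adjusted p = 0.202), and it passed by DESeq2 (3.17e-04) and without replicate 20 (7.44e-04) or 21 (0.0362). Adra2a, the alpha-2A adrenergic receptor, was at -1.12 ± 0.23 and passed by DESeq2 (adjusted p = 0.0164) and in the fit of the 2 groups (0.00706).

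The p53 list, with Cdkn1a and Phlda3 (1.97 ± 0.58) passing when adjusted over the list alone, was called as higher in the Littman line (20 of 28 members, median 0.038, adjusted p = 0.0481; adjusted p = 0.515 with an estimated correlation). The homeostatic list (20 of 25, median 0.027, adjusted p = 0.0481; adjusted p = 0.869 with an estimated correlation; Fcrls at 0.23 ± 0.079) and the inflammatory list (17 of 22, median 0.095, adjusted p = 0.0156; adjusted p = 0.717 with an estimated correlation; the chemokine Ccl2 at 0.82 ± 0.36) were called as higher too. Each of these 3 calls was lost without single libraries. The p53 call was lost without replicate 19, 22, 23, 24 or 25 (adjusted p = 0.0814 to 0.207) and with no filter (0.0620). The homeostatic call was lost without replicate 18, 20, 21, 22, 24, 25 or 26 (0.0508 to 0.894) and with no filter (0.0620). The inflammatory call was lost without replicate 22, 23, 24 or 25 (0.0574 to 0.200).

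**Figure D2:**
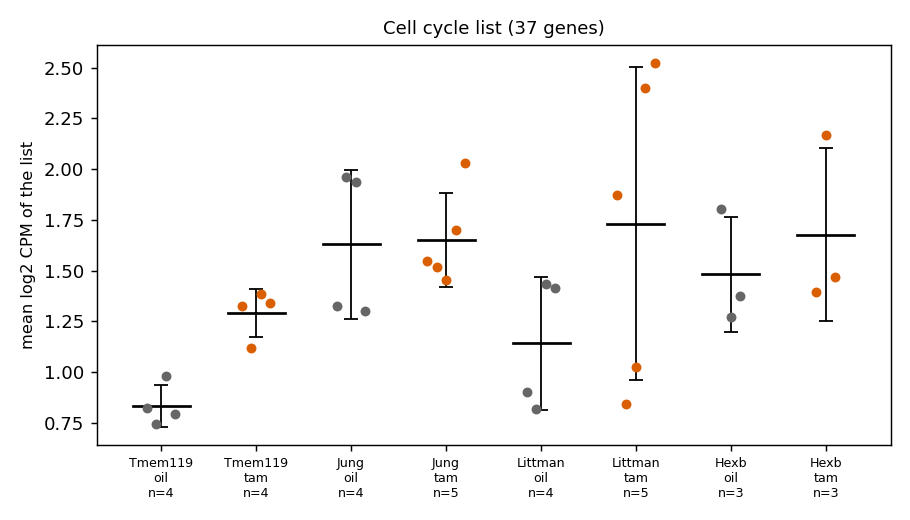
Cell cycle list score (mean log2 CPM of 37 genes, 1 point per library; grey, oil; orange, tamoxifen; bars, mean and SD) in the 8 groups. The 4 Tmem119 tamoxifen libraries lie above the 4 oil libraries (means 1.29 and 0.83), and the Littman tamoxifen libraries spread from 0.84 to 2.52.

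In the Hexb line, disease-associated microglia genes were higher after tamoxifen as a list (25 of 26 members, median 0.26, adjusted p = 3.46e-10; adjusted p = 0.156 with an estimated correlation). The secreted phosphoprotein osteopontin, Spp1, was at 1.64 ± 0.42, the tetraspanin Cd63 at 0.34 ± 0.098 and the pattern receptor Clec7a at 0.85 ± 0.28 (n = 3 and 3), and these 3 passed when adjusted over the list alone, against 0 over all genes. Immediate early genes, which also respond to tissue dissociation, were higher (29 of 31, median 0.56, adjusted p = 1.36e-09; adjusted p = 0.246 with an estimated correlation), with Zfp36 at 0.65 ± 0.16 and Junb at 0.61 ± 0.18 among the 3 that passed over the list alone. Without replicate 32 the immediate early list had an adjusted p of 0.0109. Its score differed by 0.52, with overlap between the groups (exact permutation p = 0.2). The disease-associated score differed by 0.39 with no overlap (exact permutation p = 0.1, the smallest that 3 against 3 can give). Both had a Benjamini-Hochberg value of 0.943 over all lists and lines. Among single genes, Cds2, an enzyme of phosphatidylinositol synthesis, was at -0.44 ± 0.080 (adjusted p = 0.0896). It passed by DESeq2 (5.72e-04), with no filter (0.0439), with the strict filter (0.0274) and without oil replicate 30 (0.0185). Dip2b (-0.42 ± 0.089) passed by DESeq2 (0.0143) and with no filter (0.0439), and Tmem127 (-0.60 ± 0.13), Anp32a (0.76 ± 0.17) and Hebp1 (-2.22 ± 0.49) were among the 9 that passed by DESeq2. Without replicate 30 the count of genes that passed was 9, Tmem127 (0.0287) and Hebp1 (0.00288) among them.

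Other lists were called in the Hexb line with less hold. Inflammatory genes (19 of 22 higher, median 0.18, adjusted p = 0.0114; Ccl7 at 2.02 ± 0.65), lysosome genes (26 of 34 higher, median 0.082, adjusted p = 0.0149) and markers of astrocytes (11 of 12 higher, median 1.25, adjusted p = 0.0178), neurons (10 of 12 higher, median 0.56, adjusted p = 0.0238) and erythroid cells (5 of 5 higher, median 0.82, adjusted p = 0.00458) were higher, and interferon genes were lower (30 of 40, median -0.15, adjusted p = 0.0153). With an estimated correlation these had adjusted p = 0.717, 0.869, 0.778, 0.717, 0.717 and 0.886. Adjusted over the list alone, the astrocyte gene Aldoc (2.20 ± 0.66) and the viral RNA sensor Ddx58 (-0.29 ± 0.079) passed. Tamoxifen replicate 32 stood apart with scores of 2.25 for astrocyte, 5.30 for neutrophil and 3.89 for border-associated macrophage markers and 4.90 for immediate early genes, against -0.33 to 0.10, -2.24 to 2.21, 0.39 to 1.64 and 3.95 to 4.12 in replicates 31 and 33. Without replicate 32 the calls were lost for the inflammatory (adjusted p = 0.452), neuron (0.338) and erythroid (0.230) lists and the astrocyte list turned lower (0.833). The interferon call turned to higher without replicate 27 (0.963) and was lost without 33 (0.452). Without replicate 27 the inflammatory call was lost (0.184), and the lysosome call was lost without 27 (0.0941), 30 (0.104) or 31 (0.559). Without replicate 30 the astrocyte (0.263), neuron (0.405) and erythroid (0.683) calls were lost.

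Averaged over the 4 lines, cell cycle genes were higher after tamoxifen as a list (36 of 37 members, median 0.31, adjusted p = 1.33e-15; adjusted p = 0.330 with an estimated correlation). Ube2c, at 1.18 ± 0.33, passed when adjusted over the list alone, and the kinetochore gene Cenpf was at 0.80 ± 0.25. Disease-associated microglia genes were higher by little (23 of 26, median 0.054, adjusted p = 1.92e-06; adjusted p = 0.286 with an estimated correlation), and the cystatin Cst7 (0.29 ± 0.086) passed over the list alone. No gene passed over all genes in edgeR (734 at an unadjusted p under 0.05; 0 by DESeq2 and 0 by limma voom). Among the smallest p values were those of the chromatin assembly gene Chaf1b (0.75 ± 0.17), Cds2 (-0.15 ± 0.035), Adra2a (-0.51 ± 0.12), Brd3 (0.19 ± 0.050) and the DNA repair gene Rad51ap1 (0.55 ± 0.15). With treatment permuted within lines, the mean difference in cell cycle score was 0.32, with the tamoxifen mean higher in 4 of 4 lines (exact permutation p = 0.0287, Benjamini-Hochberg 0.480 over 22 lists). The disease-associated microglia score differed by 0.13, with the tamoxifen mean higher in 3 of 4 lines (exact permutation p = 0.0913, Benjamini-Hochberg 0.649). The p53 score differed by 0.080 (exact permutation p = 0.0436, Benjamini-Hochberg 0.480). With the median over members it turned lower in Jung (-0.045) and Hexb (-0.11).

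Immediate early (27 of 31 higher, adjusted p = 0.0178), inflammatory (17 of 22 higher, adjusted p = 0.0481), neutrophil (9 of 12 lower, adjusted p = 0.0153) and neuron lists (12 of 12 higher, adjusted p = 0.0319) were also called in the average, with adjusted p = 0.778, 0.778, 0.778 and 0.752 with an estimated correlation. Single libraries ended each of these 4 calls. The immediate early call was lost without replicate 10, 17, 22, 25, 27, 30 or 32 (adjusted p = 0.0509 to 0.709) and the inflammatory call without replicate 2, 3, 5, 9, 10, 11, 14, 16, 17, 22, 23, 24, 25, 27 or 32 (0.0619 to 0.246). The neutrophil call was lost without replicate 1, 2, 14, 15, 25, 26, 31 or 34 (0.0506 to 0.228) and the neuron call without replicate 3, 4, 6, 10, 11, 18, 25, 26, 30 or 32 (0.0660 to 0.230).

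The test of whether the tamoxifen effect differed among the 4 lines passed for 0 genes in edgeR (1054 at an unadjusted p under 0.05; 0 by limma voom). It passed for 3 by DESeq2, the histone chaperone gene Anp32a (adjusted p = 0.0111), the kinesin gene Kif3b (0.0143) and the gene model Gm26930 (0.0111). Between the 2 Cx3cr1 alleles, 0 genes passed (877 at an unadjusted p under 0.05; 0 by DESeq2 and 0 by limma voom). The centrosomal gene Mphosph9 (0.53 ± 0.14, Jung minus Littman) and Brd3 (0.47 ± 0.13) were among the 10 smallest p values. As lists, 7 of 22 differed. The cell cycle effect was lower in Jung than in Littman mice for 37 of 37 members (median -0.75, adjusted p = 5.78e-10; adjusted p = 0.350 with an estimated correlation). The interferon effect was lower for 32 of 40 (median -0.31, adjusted p = 6.11e-05; adjusted p = 0.350 with an estimated correlation). Across genes, which are not independent replicates, Pearson's r between the tamoxifen effects of 2 lines ranged from -0.14 (Jung and Hexb) to 0.094 (Jung and Littman), and all 6 values lay within the range of 99 permutations of treatment within lines.

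Among oil mice, 1622 genes differed between the Tmem119 and Jung lines, 803 higher and 819 lower in Tmem119 (n = 4 and 4). Markers of other myeloid cells were lower in Tmem119 as lists: 10 of 11 monocyte genes passed as lower (adjusted p = 1.72e-07), as did 9 of 12 neutrophil genes (adjusted p = 4.50e-05) and 7 of 13 border-associated macrophage genes (adjusted p = 6.13e-06). With an estimated correlation these lists had adjusted p = 0.232, 0.331 and 0.384. The monocyte chemokine receptor Ccr2 had a log2 fold change of -2.42 ± 0.52, the endocytic adaptor Dab2 -1.05 ± 0.26 and the neutrophil alarmin S100a9 -5.78 ± 1.62. Interferon response genes were lower (35 of 40, 8 passing, median -0.47, adjusted p = 3.66e-07; adjusted p = 0.331 with an estimated correlation), among them the antiviral membrane protein Ifitm3 at -2.30 ± 0.51. So were antigen presentation genes (4 passing lower and 1 higher of 22, adjusted p = 0.00124; adjusted p = 0.457 with an estimated correlation), with the MHC class II genes Cd74 at -2.02 ± 0.49 and H2-Ab1 at -2.30 ± 0.56. Cell cycle genes were lower (32 of 37, 5 passing, median -0.53, adjusted p = 1.08e-07; adjusted p = 0.331 with an estimated correlation), with the chromatin protein Hmgb2 at -1.09 ± 0.13. Disease-associated microglia (3 passing, adjusted p = 0.00187; Lgals3 -3.24 ± 0.66, Lyz2 -1.97 ± 0.43), p53 (3 passing, adjusted p = 0.00508; Rrm2b -0.65 ± 0.14), immediate early (4 passing, adjusted p = 0.0124; Klf6 -0.40 ± 0.069), cholesterol synthesis (3 passing, adjusted p = 0.00581; Msmo1 -0.35 ± 0.078) and erythroid genes (1 passing, adjusted p = 0.00184) were lower as well. With an estimated correlation these 5 had adjusted p = 0.331, 0.184, 0.489, 0.232 and 0.377.

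Genes higher in Tmem119 than in Jung mice included the splicing factors Prpf19 (2.46 ± 0.59) and Raly (2.21 ± 0.47) and Kctd12 (1.40 ± 0.26). The groups did not overlap for 12.8% of all tested genes, against 2.86% by chance. Among the genes named for this pair, the groups overlapped for Ccr2, Ifitm3, Lgals3 and Lyz2. Monocyte scores were 3.24 to 4.08 in Jung oil replicates 11, 12 and 14, -0.10 in replicate 17 and -1.33 to -0.23 in the Tmem119 oil libraries. Replicate 17 also lay within the range of the Tmem119 oil libraries for interferon genes (2.36 against 2.24 to 2.81). The same held for border-associated macrophage markers (1.75 against 1.30 to 2.51). Replicates 11, 12 and 14 were at 3.18 to 3.34 and 4.14 to 4.36. List tests between lines were not run without replicates 9 to 14 or with a term for the 2 sets of Jung libraries. Without replicates 9 to 14, which leaves replicate 17 as the only Jung oil library and assumes that it varies like the others, 81 genes passed, and of the genes named here for this pair Tmem119, Cx3cr1, Hmgb2, Klf6 and Rrm2b kept their calls. In that fit Prpf19 (3.41), Raly (2.42) and Kctd12 (1.50) lost their calls with no smaller fold change, and Ifitm3 turned higher (0.40). Fitting only the 2 groups gave 482 genes and ended the calls of Ifitm3 (adjusted p = 0.184), Lgals3 (0.111), Lyz2 (0.110), H2-Ab1 (0.0899), Cd74 (0.0730) and Ccr2 (0.0793). By limma voom the calls of Ifitm3 (0.0539), Lgals3 (0.0584) and S100a9 (0.376) were lost. Without Tmem119 replicate 8 the count was 854, and the S100a9 call was lost without replicate 5 (adjusted p = 0.0662), 7 (0.0812) or 8 (0.0770). Without replicate 12 the disease-associated (adjusted p = 0.175), immediate early (0.137), antigen presentation (0.309) and cholesterol (0.105) calls were lost, and without replicate 6 the immediate early call was lost (0.0552).

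**Figure D3:**
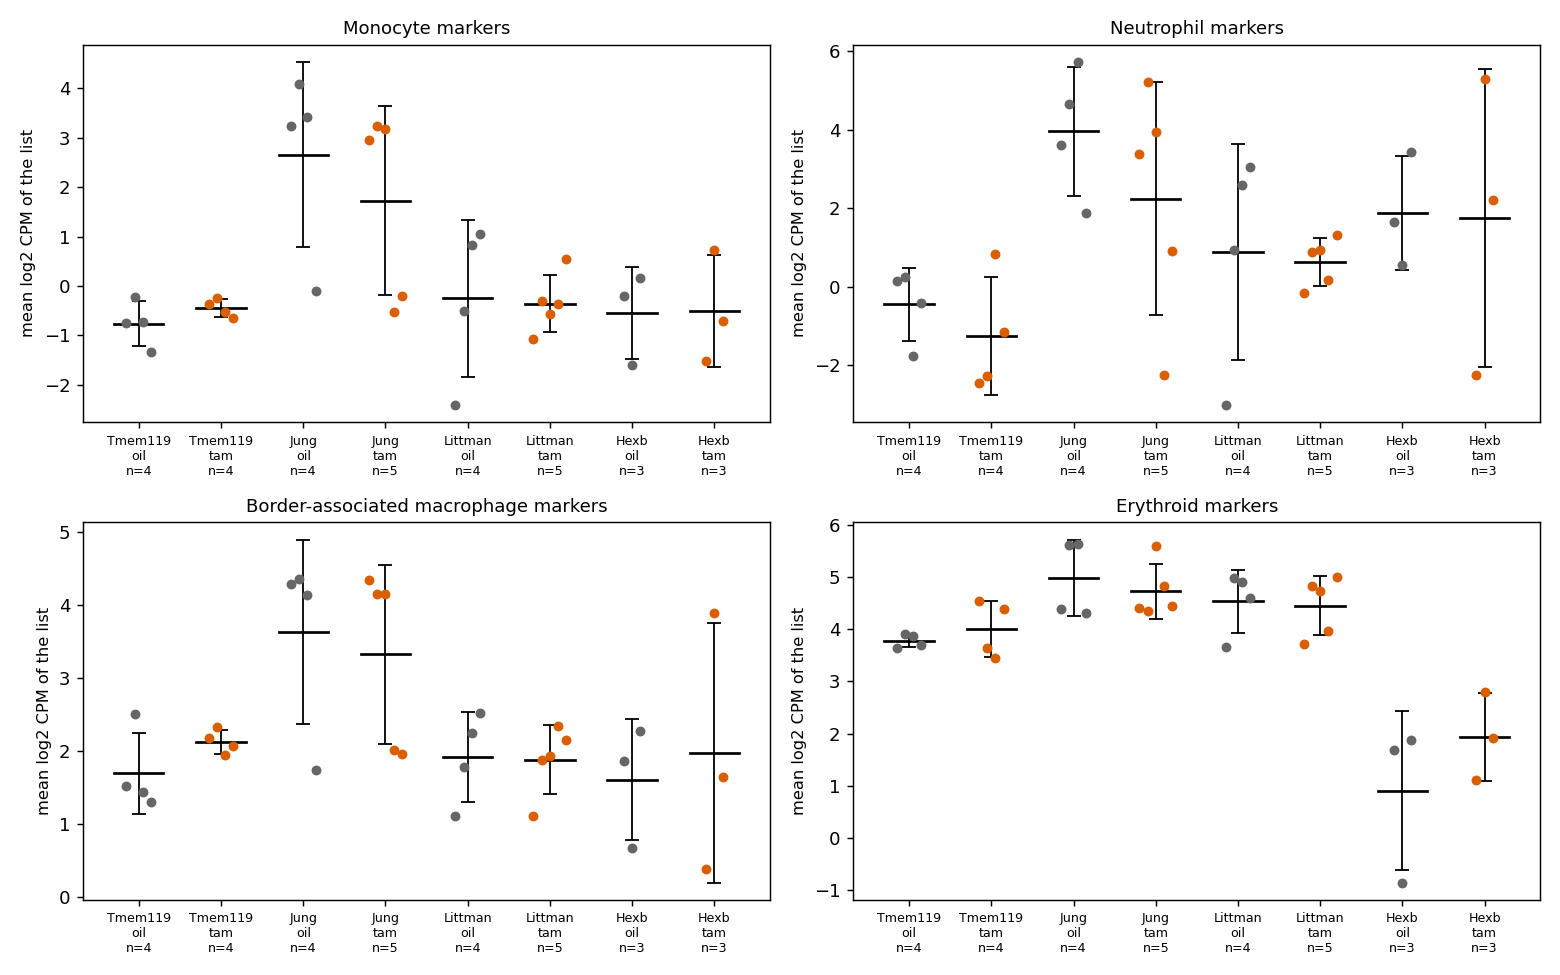
Scores of marker lists (mean log2 CPM, 1 point per library; grey, oil; orange, tamoxifen; bars, mean and SD) in the 8 groups. In the Jung line, replicates 9 to 14 have monocyte scores of 2.96 to 4.08 and replicates 15 to 17 of -0.52 to -0.10, and erythroid scores are -0.85 to 2.80 in the Hexb line and 3.45 to 5.63 in the others.

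Between the Tmem119 and Littman lines, 2581 genes differed in oil mice, 1128 higher and 1453 lower in Tmem119 (n = 4 and 4). The transcriptional corepressor gene Nab1 was at -1.27 ± 0.13 (adjusted p = 6.53e-07), the adaptor gene Cd2ap at -1.24 ± 0.17 (adjusted p = 2.89e-05), Nudt12 at -1.59 ± 0.29 and mt-Co3, a mitochondrial cytochrome oxidase subunit, at -1.26 ± 0.22. The chemokine receptor Ccr1 was at 1.47 ± 0.29. p53 response genes were lower in Tmem119 as a list (4 of 28 passing, median -0.10, adjusted p = 0.0275; adjusted p = 0.232 with an estimated correlation), led by the p53 inhibitor Mdm2 (-0.72 ± 0.12) and Rrm2b (-0.84 ± 0.14). Lysosome genes were higher in Tmem119 (6 passing higher and 3 lower of 34, median 0.14, adjusted p = 0.00906; adjusted p = 0.623 with an estimated correlation), Naglu at 0.33 ± 0.091 among them. Neuronal markers were higher (3 of 12 passing, median 1.58, adjusted p = 2.42e-04; adjusted p = 0.232 with an estimated correlation), among them the synaptic vesicle gene Syt1 (3.39 ± 0.88; mean log2 CPM -1.45). Tmem119 oil libraries also detected more genes (23927 to 26751 against 20404 to 21747 in Littman oil) and more olfactory and vomeronasal receptor genes (105 to 214 against 22 to 77). The groups did not overlap for 19.0% of all tested genes, against 2.86% by chance. Without replicate 25 the count was 1117, the lysosome call was lost (adjusted p = 0.129) and so was that of Naglu (0.0738), which was also lost without replicate 7 (0.0530), 8 (0.0626) or 22 (0.0564). The p53 call was lost without replicate 5 (0.117) or 26 (0.0674).

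Against the Hexb line, 7137 genes differed in Tmem119 oil mice (3525 higher and 3612 lower in Tmem119), 7259 in Jung (3724 and 3535) and 3809 in Littman (1961 and 1848), with n = 4 and 3 in each. Those that also differed by over 1 log2 were 1703, 1666 and 559, against 764 for Tmem119 versus Jung and 731 for Tmem119 versus Littman. Without Littman replicate 19 the count against Littman was 2532. The 3 comparisons share the 3 Hexb oil libraries, so they are not independent of each other. The groups did not overlap for 43.2% of all tested genes in Tmem119, 37.4% in Jung and 26.0% in Littman versus Hexb, against 5.71% by chance. The 100 most abundant genes held 26.9 ± 0.40% of counts (SD) in Hexb oil libraries. They held 32.3 ± 0.26% in Tmem119, 32.4 ± 1.12% in Jung and 30.6 ± 1.28% in Littman oil libraries. The lists below were not set against genes of like level, so the part of a general shift of abundant transcripts in their calls was not tested.

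Lysosome genes were higher in each of the other lines than in the Hexb line. In Tmem119 mice 26 of 34 passed as higher and 1 as lower (median 0.45, adjusted p = 6.62e-18), in Jung 28 and 1 (median 0.42, adjusted p = 3.98e-18) and in Littman 23 and 1 (median 0.31, adjusted p = 7.26e-22). Each had an adjusted p = 0.184 with an estimated correlation. Hexb itself is on the list, and the 3 calls held without the carrier genes. The lysosomal mannosidase Man2b1 was higher by 0.74 ± 0.074 in Tmem119, 0.74 ± 0.074 in Jung and 0.60 ± 0.074 in Littman mice. Naglu, which degrades heparan sulfate, was higher by 0.91 ± 0.10 in Tmem119 and 0.89 ± 0.10 in Jung, and the galactosidase Glb1 by 0.55 ± 0.071 in Tmem119 and 0.55 ± 0.071 in Littman. Gm2a, the activator of the enzyme that Hexb forms, was higher by 0.69 ± 0.080 in Jung mice.

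**Figure D4:**
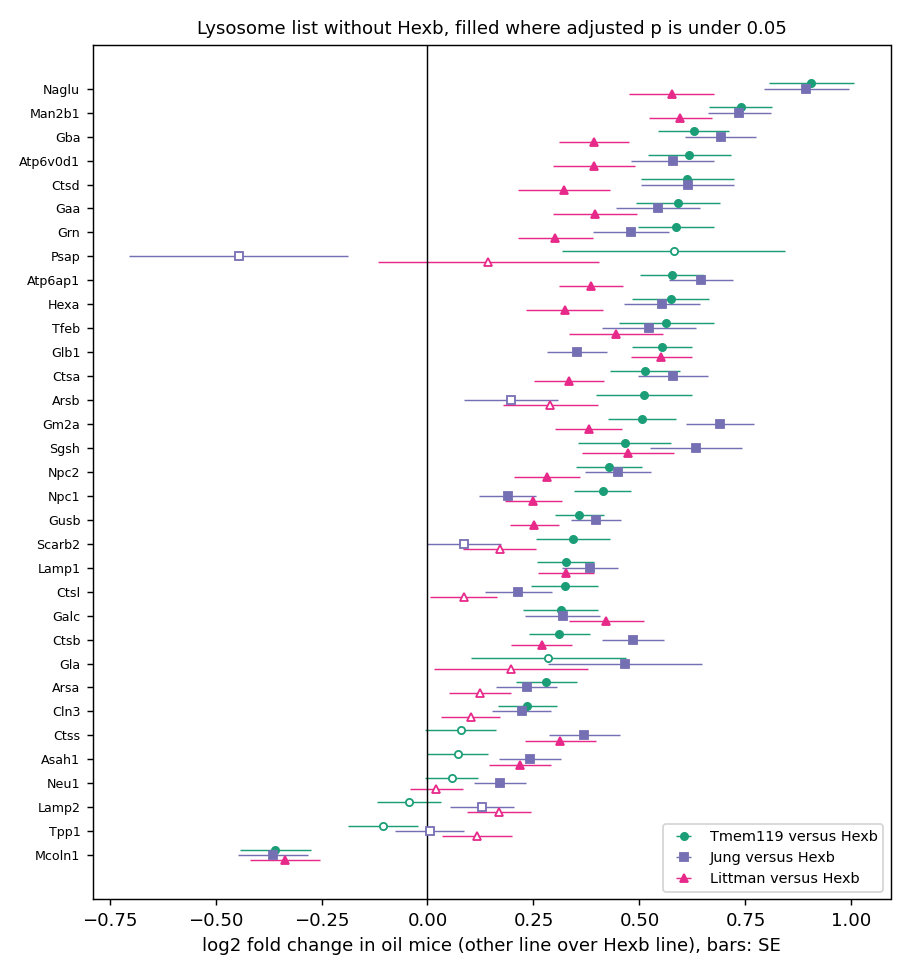
Log2 fold change (other line over Hexb line, oil mice; bars, SE; n = 4 and 3) of the lysosome list without Hexb, filled where the gene passed. Naglu is at 0.91 in Tmem119 and 0.89 in Jung, Man2b1 at 0.60 to 0.74, and 26, 28 and 23 list members, Hexb included, passed as higher in Tmem119, Jung and Littman.

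Homeostatic microglia genes were higher in Tmem119 (13 of 25 passing higher and 4 lower, median 0.31, adjusted p = 1.05e-06), Jung (15 and 4, median 0.33, adjusted p = 1.80e-07) and Littman mice (7 and 1, median 0.19, adjusted p = 3.80e-09) than in Hexb mice, with adjusted p = 0.232, 0.232 and 0.184 with an estimated correlation. The list includes the carrier genes Tmem119, Cx3cr1 and Hexb. Hexb (5.74 in Tmem119, 5.87 in Jung and 5.77 in Littman) is among the members that passed as higher and adds to these calls. Csf1r, the receptor microglia need to survive, was higher by 0.64 ± 0.079 in Tmem119, 0.63 ± 0.079 in Jung and 0.52 ± 0.079 in Littman, and the lipid receptor Trem2 by 0.52 ± 0.075 and the fructose transporter Slc2a5 by 0.57 ± 0.088 in Tmem119. Tmem119 was higher by 0.57 ± 0.098 in Jung (adjusted p = 2.56e-05) and 0.30 ± 0.097 in Littman (adjusted p = 0.0251) and was at -0.24 ± 0.096 in the Tmem119 line (adjusted p = 0.0488). Cx3cr1 was at -0.65 ± 0.10 in Jung and -0.76 ± 0.10 in Littman. The Tmem119 call in the Tmem119 line was lost without any 1 of its 7 libraries, replicates 5, 6, 7, 8, 27, 30 and 34 (adjusted p = 0.0594 to 0.0987), by DESeq2 (0.0618) and with DESeq2's size factors (0.0648). In the Littman line it was lost without replicate 19, 26, 27, 30 or 34 (0.0592 to 0.139) and in the fit of the 2 groups (0.0987).

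Disease-associated microglia genes were higher too, with 14 of 26 passing higher and 2 lower in Tmem119 (median 0.36, adjusted p = 2.64e-04), 20 and 1 in Jung (median 0.63, adjusted p = 8.14e-08) and 11 and 0 in Littman (median 0.39, adjusted p = 1.30e-05), and adjusted p = 0.243, 0.184 and 0.232 with an estimated correlation. The chemokine Ccl6 was higher by 0.98 ± 0.11 in Jung and 0.65 ± 0.11 in Littman, and Cd68 (0.63 ± 0.091), Cd63 (0.62 ± 0.093) and the cathepsin Ctsz (0.58 ± 0.084), all of the endolysosome, in Tmem119. Inflammatory genes were higher, with 9 of 22 passing higher and 2 lower in Tmem119 (adjusted p = 0.0313), 9 and 1 in Jung (adjusted p = 0.00335) and 5 and 1 in Littman (adjusted p = 0.0347), and adjusted p = 0.471, 0.331 and 0.474 with an estimated correlation. The adhesion molecule Icam1 was higher by 0.89 ± 0.10 in Tmem119, 0.86 ± 0.10 in Jung and 0.67 ± 0.10 in Littman and Tlr2 by 0.71 ± 0.12 in Tmem119. The inflammatory call was lost in Tmem119 without replicate 27 (0.113) or 34 (0.0816) and in Littman without replicate 26 (0.0814), 27 (0.140) or 34 (0.0816).

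Cholesterol synthesis genes were higher in Jung (12 of 24 passing higher and 1 lower, adjusted p = 7.77e-04) and Littman mice (7 and 1, adjusted p = 0.00949) than in Hexb mice, with adjusted p = 0.184 and 0.232 with an estimated correlation. Dhcr7, the last enzyme of the pathway, was higher by 0.90 ± 0.10 in Jung and 0.70 ± 0.10 in Littman, and the sterol reductase Tm7sf2 was at -1.24 ± 0.21 in Littman. Antigen presentation genes were higher in Jung mice (12 of 22 passing higher and 1 lower, adjusted p = 0.00154; adjusted p = 0.470 with an estimated correlation), with the class II chaperone H2-DMb1 at 0.84 ± 0.086. Interferon genes were lower in Tmem119 (12 of 40 passing lower and 1 higher, adjusted p = 0.0217) and Littman mice (3 and 0, adjusted p = 0.00999) than in Hexb mice, with adjusted p = 0.688 and 0.665 with an estimated correlation. Phf11d (-0.67 ± 0.12) and the retrovirus restriction gene Trim30a (-0.61 ± 0.11) led in Tmem119, and Trim30a was at -0.54 ± 0.11 in Littman. The interferon calls were lost without Hexb replicate 27 (0.209 in Tmem119, 0.307 in Littman) and, in Tmem119, without replicate 5 (0.0811).

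Erythroid markers were higher in the other lines than in Hexb mice, 5 of 5 passing in each (adjusted p = 0.00154 in Tmem119, 1.30e-05 in Jung, 4.88e-08 in Littman; adjusted p = 0.370, 0.232 and 0.184 with an estimated correlation). The globin gene Hba-a2 was higher by 2.59 ± 0.50, 4.09 ± 0.51 and 3.50 ± 0.50. Monocyte (9 of 11 passing, adjusted p = 0.0113; adjusted p = 0.557 with an estimated correlation) and border-associated macrophage markers (8 of 13 passing higher and 1 lower, adjusted p = 0.0275; adjusted p = 0.697 with an estimated correlation) were higher in Jung than in Hexb mice, with Treml4 at 5.92 ± 1.18. The macrophage call was lost without replicate 11 (0.0596), 14 (0.0612) or 30 (0.0715), and without Jung replicates 9 to 14 the Treml4 call was lost (0.288) and 3202 genes passed. The share of counts on mitochondrial genes was 0.173 ± 0.019% in Hexb oil libraries and 0.0958 ± 0.0037% in Tmem119, 0.103 ± 0.012% in Jung and 0.105 ± 0.021% in Littman oil libraries.

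The largest single differences from the Hexb line included 2 receptors of adrenergic and immune signals that were higher in the other lines: Adra2a (1.88 ± 0.27 in Tmem119, 1.85 ± 0.27 in Littman) and Pdcd1, which encodes PD-1 (1.98 ± 0.31 in Tmem119). The clock repressor Nr1d1 was higher by 1.83 ± 0.23 in Tmem119 and 1.50 ± 0.22 in Littman. Lower than in Hexb mice were the nuclear noncoding RNA Firre (-2.55 ± 0.36 in Tmem119, -2.62 ± 0.36 in Jung), Arglu1 (-2.39 ± 0.22 in Tmem119, -2.44 ± 0.22 in Jung, -1.57 ± 0.22 in Littman), the RNA processing genes Pnisr (-2.34 ± 0.28) and Srsf5 (-2.32 ± 0.27) in Tmem119, and Gpc2 (-2.00 ± 0.36) and Pde1b (-1.85 ± 0.31) in Littman.

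The 2 Cx3cr1 alleles were the closest pair. In oil mice 805 genes differed, 447 higher and 358 lower in Jung (n = 4 and 4), and in tamoxifen mice 3 did, all of which also passed in oil mice: the lysosomal nuclease Dnase2a (0.67 ± 0.078 in oil, adjusted p = 1.29e-05; 0.49 ± 0.070 in tamoxifen, adjusted p = 2.95e-04), the collagen-modifying gene Crtap (0.65 ± 0.089, adjusted p = 1.42e-04; 0.63 ± 0.080, adjusted p = 3.79e-05) and the microtubule gene Clasp2 (0.68 ± 0.089, adjusted p = 1.03e-04; 0.65 ± 0.080, adjusted p = 3.60e-05). These 3 were chosen after their values were seen. Clasp2 (113741473 to 113919682) and Crtap (114375134 to 114390675) lie on chromosome 9, 5.98 and 5.51 Mb from Cx3cr1, and Dnase2a lies on chromosome 8. Dnase2a passed in all 15 alternatives run on the oil comparison (adjusted p up to 0.0267), Clasp2 in 14 and Crtap in 13.

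Antigen presentation genes were higher in Jung than in Littman oil mice (21 of 22, 5 passing, median 0.41, adjusted p = 2.27e-08), with Tap1 at 0.47 ± 0.11 and H2-M3 at 0.46 ± 0.11. Also higher were interferon genes (32 of 40, 6 passing, adjusted p = 1.30e-05; Ifitm3 2.48 ± 0.51, Irf7 1.05 ± 0.24), disease-associated microglia genes (21 of 26, 2 passing, adjusted p = 3.88e-06; Lyz2 1.75 ± 0.43), monocyte (11 of 11, 3 passing, adjusted p = 6.60e-07; Treml4 4.59 ± 0.95), border-associated macrophage (12 of 13, 2 passing, adjusted p = 2.88e-06) and neutrophil markers (12 of 12, 2 passing, adjusted p = 0.00124). With an estimated correlation these had adjusted p = 0.232, 0.421, 0.232, 0.232, 0.370 and 0.422. Cell cycle (0 passing, adjusted p = 2.97e-04), cholesterol (2, 0.00260; the LDL receptor Ldlr 1.42 ± 0.33), lysosome (4, 0.00108; Gm2a 0.31 ± 0.073), inflammatory (0, 0.00618), astrocyte (1, 0.00277) and neuron lists (0, 0.00715) were higher in Jung too, with adjusted p = 0.498, 0.232, 0.491, 0.370, 0.422 and 0.331 with an estimated correlation. The urokinase receptor Plaur (0.89 ± 0.14) and the membrane protein Stom (0.78 ± 0.12) were higher, and Kctd12 (-1.16 ± 0.26) and the RNA-binding genes Tardbp (-0.73 ± 0.14) and Pabpn1 (-0.74 ± 0.14) were lower. The groups overlapped for Ifitm3, Irf7, Lyz2 and Treml4.

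The count of 805 fell to 14 without Jung replicate 12, 17 without Littman replicate 25 and 85 without Littman replicate 22, and rose to 1545 without Littman replicate 19. It was 1 in the fit of the 2 groups, Dnase2a. Without Jung replicates 9 to 14 it was 2, Dnase2a and Clasp2. Tap1, H2-M3, Ifitm3, Irf7, Lyz2, Treml4, Ldlr, Gm2a and Kctd12 lost their calls without replicate 12 (adjusted p = 0.127 to 0.207), 22 (0.0504 to 0.0852) or 25 (0.0544 to 0.125). Kctd12 stayed at -1.13, -1.08 and -1.11 in these fits and was at -1.25 without replicates 9 to 14, where Ifitm3 (-0.21), Irf7 (0.027), Lyz2 (-0.0998) and Treml4 (-0.0016) lost the difference itself. Tardbp and Pabpn1 lost their calls without 12 (0.0898 and 0.0711) or 25 (0.0544 for both), with Tardbp at -0.64 in both and Pabpn1 at -0.60 and -0.59. Plaur and Stom lost theirs in the fit of the 2 groups (0.152 for both), where they were still at 0.89 and 0.77, and without replicates 9 to 14, where Plaur was at 0.50 and Stom at 0.32 (0.970 for both). By limma voom Tap1, H2-M3, Ifitm3, Irf7, Lyz2, Treml4, Ldlr and Kctd12 lost their calls (0.0504 to 0.274). The inflammatory call was lost without replicate 12 (0.0589), the lysosome call without 25 (0.104) and the neuron call without 26 (0.0536). Monocyte scores in Jung oil mice were 3.24, 4.08, 3.41 and -0.10 in replicates 11, 12, 14 and 17, and in Littman oil mice -2.40, -0.50, 0.84 and 1.06 in replicates 19, 22, 25 and 26.

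None of the line tests of the estrogen response (smallest adjusted p = 0.120), lymphocyte (0.0701), oligodendrocyte (0.120), oligodendrocyte precursor (0.138), endothelial and mural (0.627) and choroid plexus and ependyma lists (0.157) passed. A knock-in can carry linked sequence of another strain, so genes within 5 Mb of each carrier gene were compared with all others. In 0 of 18 tests were they called more or less often (Fisher's exact test, smallest p = 0.105, for Cx3cr1 in Tmem119 versus Littman, where 19 of 98 flanking genes passed against 13.7% of others, Benjamini-Hochberg 0.976). Some of these tests pair lines that both lack an insertion at the locus. Clasp2 and Crtap, at 5.98 and 5.51 Mb from Cx3cr1, lie outside the 5 Mb window, so these 18 tests do not cover them. The alternative window of 10 Mb includes both, and its results are not given here.

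Oil and tamoxifen mice are separate libraries, so the line differences were compared between them. Of the genes called in oil mice, the share with the same sign in tamoxifen mice was 97.4% for Tmem119 versus Jung, 98.7% for Tmem119 versus Littman, 98.4% for Tmem119 versus Hexb, 96.8% for Jung versus Littman, 95.2% for Jung versus Hexb and 98.2% for Littman versus Hexb. Called in both were 746, 1434, 5203, 3, 3793 and 2673 genes, against 71.4, 198, 1356, 0.0712, 893 and 435 for independent calls in the same direction. Pearson's r of the fold changes over the called genes, across genes and not independent replicates, ranged from 0.788 (Littman versus Hexb) to 0.927 (Tmem119 versus Jung). Over all tested genes r was 0.263 for Littman versus Hexb, 0.384 for Jung versus Littman, 0.408 for Jung versus Hexb and 0.752 to 0.805 for the pairs with Tmem119. Tmem119 libraries detected more genes on average (24962.5 in oil and 28350.5 in tamoxifen, against 20972.2 to 23002.3 in the other groups). Of the 1622 calls against Jung and 2581 against Littman, 965 and 1860 had a mean log2 CPM of at least 1. The part of low-count genes in these values was not tested. In the Jung line both treatments include libraries of each of the 2 sets, so this comparison does not separate them. Line cannot be told apart from colony, breeding or any processing batch, or, in the Hexb line, from homozygosity of the allele. Such differences would recur in tamoxifen mice, so the same sign there does not assign a difference to an allele.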

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

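The tests that weigh the cell cycle pattern below were chosen after the result was seen. Each oil or tamoxifen group of at least 4 libraries was searched for a library far from the others of its group, by Dixon's test. Chance gives about 1 in 20 groups, or 8.4 of the 168 tested (28 measures in 6 groups), and 9 were found. Jung tamoxifen replicate 10 was low for Hexb (14.22 against 14.32 in the nearest library) and for homeostatic genes (11.34 against 11.42). Jung oil replicate 17 was low for interferon genes (2.36 against 3.18), border-associated macrophage markers (1.75 against 4.14) and astrocyte markers (-0.67 against 1.05). Littman oil replicate 19 was low for interferon genes (2.25 against 2.63), Jung tamoxifen replicate 15 for antigen presentation genes (5.81 against 6.21) and Littman oil replicate 25 for cholesterol synthesis genes (3.31 against 3.39). Littman oil replicate 26 was high for estrogen response genes (4.75 against 4.59).

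The tamoxifen effect differed between the Jung and Littman lines for 7 lists, tested as a difference of effects. The medians of Jung minus Littman were -0.11 for homeostatic, -0.31 for interferon, -0.13 for disease-associated microglia, -0.75 for cell cycle, -0.20 for inflammatory, -0.17 for antigen presentation and -0.11 for lysosome genes. At the preset correlation their adjusted p values were 0.0124, 6.11e-05, 0.0124, 5.78e-10, 0.00170, 2.03e-04 and 3.71e-05, and with an estimated correlation they were 0.350 to 0.410.

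Cell cycle genes were higher after tamoxifen as a list in the Tmem119 (median 0.25) and Littman lines (median 0.70). If the same other cell type were more frequent in the tamoxifen libraries of both lines, its markers would be higher in both. Of 11 cell type lists, 0 reached the cell cycle median in both lines. Choroid plexus and ependyma markers (1.87) did so in Littman alone, and oligodendrocyte precursor (0.95) and monocyte markers (0.35) in Tmem119 alone. The test cannot weigh a different cell type in each line, or a type outside the lists, so other cells stay open. A single library is argued against by the highest adjusted p without 1 library (0.00464), and deeper sequencing by a mean depth in units of 1e6 that differed by -3.00 after tamoxifen in Littman and, in Tmem119, where it was 6.51 higher, by the call with total counts made equal in 1 thinning of the libraries (adjusted p = 8.68e-05, median 0.21), which did not match the genes detected. Background reads that raise genes with low counts in Tmem119 tamoxifen libraries are argued against by genes of the same mean log2 CPM (median 0.0047), of which 0 of 100 matched sets reached the median of the list (highest 0.14). A lasting effect of tamoxifen with CreER on division may be involved, as a hypothesis, but the call in Tmem119 was lost with no filter on low counts (0.189), neither call held with an estimated correlation, and no mice without CreER were given tamoxifen.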

How the results depend on the processing

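The term for the 2 sets of Jung libraries, the fits without or with only Jung replicates 9 to 14, the lists without carrier genes and the permutation over all lines were chosen after the data were seen. No paired analysis was possible because replicate numbers are unique to each mouse. Of the values for lists in a comparison, 813 kept direction and call, 174 lost the call and 2 reversed. For named genes 2316 were the same, 20 gained a call, 109 lost it and 4 reversed. Of the summary counts 321 stayed within 1.5 times and 39 moved. The cause was not tested except where fewer libraries were fitted. DESeq2's size factors shifted the median log2 fold change by at most 0.022, but the share of called genes that were higher in Tmem119 moved from 43.7 to 51.1% against Littman and from 49.5 to 55.3% against Jung. At these depths and group sizes, 46.3 to 79.1% of simulated 1.5-fold changes were recovered, so smaller changes can be missed.

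Where 0 genes passed by edgeR after tamoxifen, with 578 in Littman, 1234 in Hexb and 1054 for the difference between lines at an unadjusted p under 0.05, DESeq2 gave 2, 9 and 3, and limma voom 0 in each. The 2-group fit gave 1 in Littman, and Hexb gave 2 with no filter and 1 with the strict filter. In oil mice, Tmem119 versus Jung gave 482 in the 2-group fit and 81 without replicates 9 to 14. Jung versus Littman gave 126 by limma voom, 1528 by DESeq2, 1 in the 2-group fit and 2 without replicates 9 to 14, and Jung versus Hexb then gave 3202. Those fits keep 1 Jung oil library, assumed to vary like the others. In them Ifitm3 reversed to 0.40 in Tmem119 versus Jung, and in Jung versus Littman Ifitm3 to -0.21, Lyz2 to -0.0998 and Treml4 to -0.0016. With an estimated correlation 0 list tests passed of the 24 tamoxifen and 48 line calls by camera. With the median over members 1 score difference instead of 2 had an exact permutation p under 0.05, and the p53 score reversed to -0.045 in Jung and -0.11 in Hexb.

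Without each library in turn, counts after tamoxifen ranged over 0 to 1 in Tmem119 (1 without replicate 1), 0 to 2 in Jung (2 without 16), 0 to 1 in Littman (1 without 20 or 21) and 0 to 9 in Hexb (9 without 30). Tmem119 versus Jung ranged over 854 (without 8) to 1675 (without 12), Tmem119 versus Littman over 1117 (without 25) to 2789 (without 19), Jung versus Littman over 14 (without 12) to 1545 (without 19), with 17 without 25 and 85 without 22, and Littman versus Hexb over 2532 (without 19) to 4336 (without 25). Tamoxifen list calls ranged over 15 (without 30) to 32 (without 31). In the Hexb line the interferon list ranged over an adjusted p of 3.52e-06 (without 34) to 0.963 (reversed, without 27) and the astrocyte list over 3.00e-05 (without 33) to 0.833 (reversed, without 32).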

Other observations

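The test of the microglial share and the test on the genes higher in Jung were chosen after the result was seen. Olfactory and vomeronasal receptor genes, 1721 in the table, had at least 1 count for 105 to 214 genes in Tmem119 oil libraries and 143 to 596 in Tmem119 tamoxifen libraries. The highest, replicate 4, had 596 at 74.7 CPM in sum, and libraries of the other lines had 22 to 265.

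Splits of the same libraries into groups of the same sizes were refitted. For tamoxifen versus oil by edgeR, the real count was 0, which any split reaches (35 of 35 in Tmem119, highest other 1; 100 of 100 in Jung, 51, and Littman, 94), so the splits decide nothing about chance. The same holds for the average effect (89), the difference among lines (22) and the Jung and Littman difference (199), with 100 of 100 each. In Hexb the 10 splits are too few for a share under 0.05 (real 0, highest other 91). The counts at an unadjusted p under 0.05 were 639, 1431, 578 and 1234 in the 4 lines, 734 for the average, 1054 among lines and 877 for Jung and Littman. The median over the other splits was 1 in Hexb and 0 elsewhere, so the highest counts come from few splits, and whether they reflect a structure of the samples was not tested.

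For line pairs in oil mice, no other split reached the real count for Tmem119 versus Jung (real 1622, highest other 84) or Tmem119 versus Littman (2581, 0). Nor did one for Tmem119 versus Hexb (7137, 4722, replicate 5 placed with the Hexb libraries) or Jung versus Hexb (7259, 5741, replicate 14 placed with them). Each was at 1 of 35 splits, the smallest share that 35 splits can give, with no correction over the pairs. The splits thus argue against chance for these pairs but cannot exclude it. The splits did not argue against chance for Jung versus Littman, where 2 of 35 reached the real 805 and the highest other was 1067 (replicates 11, 12, 17 and 19 against the rest). In tamoxifen mice 96.8% of the 805 had the same sign, but genes are not independent and 3 were called in both, so chance stays open for the count. For Littman versus Hexb 2 of 35 splits reached 3809, and the highest other was 3831 (replicate 25 placed with the Hexb libraries). There the separate tamoxifen mice argue against chance: 98.2% of the 3809 had the same sign and 2673 were called in both, against 435 if the calls were independent. Genes are not independent here either, so the excess over 435 has no p-value, and r over all tested genes was 0.263. A batch shared by all Hexb libraries would recur in the tamoxifen mice and is not excluded.

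Genes that differ between Jung and Littman oil mice may partly reflect the 2 sets of Jung libraries, replicates 9 to 14 and 15 to 17. Of the 805 genes, 61.6% had the same sign between Jung tamoxifen replicates 9, 10 and 13 and replicates 15 and 16, against 51.1% of all tested genes. The share was 64.9% for the genes higher in Jung, where other myeloid cells are a candidate source although the sort gated on intermediate CD45, and 57.5% for the 358 genes lower in Jung. The markers of those cells cannot decide, since the sets were told apart by them. Both stay open, and the sets cannot be told apart from the alleles in oil mice, where replicate 17 is the only library of its set. As a test of dilution of microglial transcripts by other cells, the homeostatic list had a median of 0.11 (SD 0.18) and the genes lower in Jung -0.45. The homeostatic list was thus not lower in Jung. The other genes were selected as lower, and scaling can remove an even dilution, so the test cannot exclude dilution for them.

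A time of day that differed between Hexb and other mice is a candidate explanation for clock genes. Beside Nr1d1 (1.83, 1.69 and 1.50 in Tmem119, Jung and Littman versus Hexb), 2 of 5 genes that cycle with it were called in all 3 comparisons, Dbp (1.61, 1.80 and 1.31) and Tef (0.89, 0.98 and 0.86). Of 4 that cycle against it, 1 was called the other way in all 3, Arntl (-0.69, -1.03 and -0.48). The prediction of at least 4 of 5 and 2 of 4 was not met, and the labels give no hour, so the question stays open.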
